A study of Mus musculus with 22 samples.

How the data were processed

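The values are the log2 signals of the deposited table, which the submitters' processing notes describe as summarized with RMA, without a version. No raw array files were processed. Groups were read from the labels: 22 arrays of 8 groups, which pair 4 days with 2 sorted subsets, 3 arrays per group except 1 for the Gr1-positive cells of day 8. All 22 columns of the table were matched to a label. The values run from 2.3432 to 13.949, so that levels near the top can be compressed, and the smallest root mean square difference between 2 arrays was 0.1407, so that no array is a copy of another. The number of arrays limits the precision.

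The table holds 35556 probe sets, of which 23410 have a gene in the platform's gene table and 12146 do not. Of the former, 21789 name 1 gene and 1621 name several and were left out. Entrez numbers matched 21698 of the probe sets to the names of the mouse reference table (GRCm38.p6 RefSeq), which was used for names only. For the 999 genes with more than 1 probe set the probe set with the highest mean was kept, which left 19938 genes. Probe sets of gene families with near-identical members, such as Klr, Ly6, Cd209, Ifit, H2 and immunoglobulin genes, can hold signal of several members, and the probe annotation can be out of date. The probe sets of Ighm and of Top2a differ in sign from each other in some comparisons. Genes not among the 19938 were not analysed here.

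Gene tests used limma 3.58.1 in R 4.3.3 (statmod 1.5.0): a linear model with 1 mean per group over all 22 arrays, moderated variances without trend, and Benjamini-Hochberg adjustment within each of 13 comparisons. A gene passed at an adjusted p under 0.05. The comparisons are the subset difference (Gr1-negative minus Gr1-positive) at days 1, 2, 4 and 8, the steps from day 1 to 2, 2 to 4 and 4 to 8 in each subset, and the change of the subset difference from day 1 to 2, 2 to 4 and 1 to 4. SE is that of the moderated fit and SD that of the arrays of a group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and random steps used seed 1.

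The shares of variance come from a balanced split of each gene's sum of squares over the 18 arrays of days 1, 2 and 4. For comparison, 19938 genes with no effect were simulated with the correlation of same-numbered arrays estimated from the data, which was added after the shares were seen. With independent arrays the simulated medians were 8.7% for day, 2.9% for subset, 8.8% for the interaction and 72.4% for replicates. Principal components were computed on all 22 arrays. For overlaps, the number shared by chance is the product of the 2 counts over 19938. Subset differences at different days share no arrays. The steps in the 2 subsets share no arrays either, but same-numbered arrays of a day deviate together. Within a day, the residuals of all 9 same-numbered pairs correlated above 0.1 (0.25 to 0.86) and all 9 matched their own number best. Across days 7 of 15 pairs were above 0.1 (-0.38 to 0.41) and 5 matched their own number best. The block therefore used day and number together for the subset differences and their changes, as a fixed term, or as a random term with an estimated correlation of 0.278.

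The 27 gene lists were written before the data were examined. The lists are the sort markers (3 of 5 members measured), inflammatory cytokines and chemokines (20 of 20), Ly6C-high monocyte genes (12 of 15), resident-type and efferocytic macrophage genes (22 of 23), alternative activation (14 of 14) and growth factors of repair (10 of 13). Metabolic and cell biology lists are cell cycle (29 of 30), glycolysis (17 of 20), hypoxia response (16 of 16), oxidative phosphorylation (27 of 28), fatty acid oxidation (16 of 17), lipid handling and nuclear receptor targets (17 of 17), lysosome (17 of 20), iron and heme handling (14 of 15) and matrix remodelling (14 of 15). MHC class II presentation (10 of 12), interferon-stimulated genes (19 of 22) and cell isolation stress genes (16 of 17) follow. Marker lists of cell types are neutrophil (15 of 16), dendritic (10 of 10), T and NK (13 of 14), B (7 of 8), mast cell and eosinophil (10 of 10), fibroblast (12 of 12), muscle (15 of 15), endothelial (9 of 9) and red cell (3 of 7). Each list was tested in each comparison with limma camera at the preset correlation of 0.01, adjusted over all 351 tests. It was tested again with a correlation estimated per list. That test was run only without the replicate block, so it does not allow for same-numbered arrays deviating together. The median, the mean and the test differ in sign in 57 of the 351 list tests, none of which was called. The growth factor list was written with knowledge of earlier work on such cells. Ly6c1 and Ly6c2, in both the sort marker and the monocyte list, were among the members not analysed.

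Genes were named by a rule written before the data were examined. It takes the sort markers, the 10 largest differences per direction (5 for changes of the subset difference) among genes past the test without overlap between the arrays of the groups and with a mean in the higher group at or above the median of all values, 7.366, and up to 4 members of each list past the test, or else up to 2 with the highest mean. Predicted genes and clone names were left out. The text names fewer than the rule allows. Of 547 names past the test, 305 kept their call whichever single array was left out and 242 lost it for at least 1 array, and of 145 list calls 92 kept theirs. The text prefers those that kept it, a preference made after the values were seen.

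Alternatives written before the data were examined were a fit with only the compared groups, an intensity trend with robust variances, array quality weights, a filter (above the median of all values in at least 3 arrays), the mean of a gene's probe sets, every probe set tested, quantile normalization of the table again, each array centred on its median, an adjusted p under 0.01, a 2-fold minimum, the replicate block as a fixed or random term, and leaving out each array in turn. For the lists, an estimated correlation, lists without shared members and camera by ranks were added. Alternatives chosen after the data were seen were a fit without both day 2 arrays numbered 1, and subset differences without the genes of the cell type marker lists.

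The code was tested on simulated data. With effects planted in simulated arrays, the day 1 subset difference recovered 69%, 90.9% and 96.8% of genes changed 1.5-fold, 2-fold and 4-fold, with 12 false calls. The day 8 subset difference recovered 25.4%, 82.4% and 95.4% with 6 false calls, and the change of the subset difference from day 1 to day 4 23.1%, 67.7% and 98.3% with 8. Without planted effects 0 genes were called in the 13 comparisons. In a paired simulation of the day 1 subset difference, 107 of 200 changed genes were called without the block and 181 with it. Those pairs shared a deviation with an SD 1.5 times that within a pair. This pairing is stronger than the correlation of 0.278 estimated here, so the gain is no measure of that in these arrays.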

Results

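The tibialis anterior muscle of C57BL/6J mice was injured with cardiotoxin, a snake venom toxin that kills muscle fibres and sets off regeneration. CD45-positive leukocytes were taken from the muscle at days 1, 2, 4 and 8 and sorted by Gr1 and Cx3cr1 into Gr1-positive Cx3cr1-low and Gr1-negative Cx3cr1-high cells, which the protocol also calls Ly6C-positive F4/80-low and Ly6C-negative F4/80-high. Genome-wide RNA levels were measured on 22 Affymetrix arrays, with 3 biological replicates per day and subset except the Gr1-positive cells of day 8, which had 1 array. Array medians lay between 7.02 and 7.18 on the log2 scale, and the number of arrays limits the precision. Levels are log2 signal as mean ± SD, with n = 3 unless stated, and differences are log2 values ± SE with limma adjusted p-values over 19938 genes.

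The design asks how the cells changed between inflammation and repair, and how the subsets differed on the way. Day took a median of 27.7% of a gene's variance over the 18 arrays of days 1, 2 and 4, subset 7.1%, their interaction 4.8% and the spread between replicates 50.7%. In simulated genes with no effect, whose same-numbered arrays of a day correlate as estimated here (0.278), the medians were 11.7%, 2.1%, 6.5% and 73.4%. Day took more than subset in 78.7% of genes, which is no more than the 79.7% of the simulated genes. Among the 10039 genes with a mean at or above the median signal, the shares were 43.5% for day, 6.8% for subset and 35.5% for replicates. The first principal component, with 42.3% of the variance of all 22 arrays, set the arrays of days 1 and 2 against those of days 4 and 8, and the second took 16.2%.

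**Figure D1:**
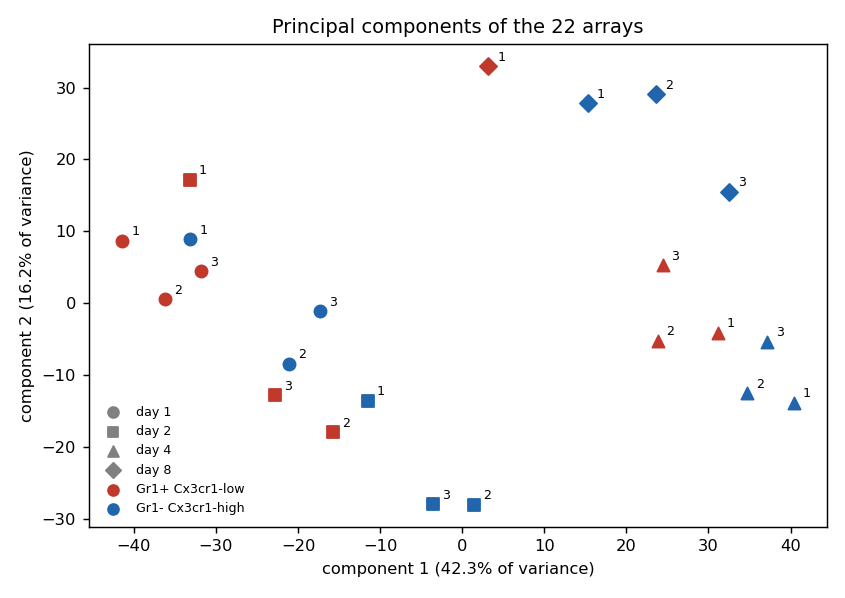
Each point is 1 of the 22 arrays on principal component 1 (42.3% of variance, horizontal) and 2 (16.2%, vertical), in units of component score, with colour for the sorted subset, shape for the day and the replicate number beside it. All day 4 arrays score 23.8 or higher on component 1, and all arrays of days 1 and 2 score 1.4 or lower.

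At day 1 the Gr1-negative cells carried higher levels of dendritic cell genes, and the Gr1-positive cells of part of the neutrophil genes. Ccr7, the receptor that guides dendritic cells to lymph nodes, stood at 11.37 ± 0.17 against 8.14 ± 0.38, 9.37-fold higher in Gr1-negative cells (log2 difference 3.23 ± 0.32, adjusted p = 2.35e-05). Ccl22, a chemokine of dendritic cells and macrophages, was 5.96-fold higher (9.59 ± 0.27 against 7.02 ± 0.11, adjusted p = 2.35e-05), and the C-type lectin gene Cd209a was 7.76-fold higher (10.82 ± 0.78 against 7.86 ± 0.59, adjusted p = 0.0063). The lectin-like receptor genes Klrd1 and Klrb1b, known from natural killer cells, were 10.8-fold and 10.7-fold higher (adjusted p = 5.88e-05 and 3.91e-07). S100a9, a calcium-binding protein abundant in neutrophils and monocytes, stood at 7.54 ± 0.37 in Gr1-negative and 9.46 ± 0.38 in Gr1-positive cells (-1.92 ± 0.25, adjusted p = 0.000364).

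Of the 10 dendritic cell markers, 6 were higher in Gr1-negative cells at day 1 and 4 did not pass, with 9 higher when adjusted over the list alone. Their median was 1.37 (adjusted p = 4.02e-20, adjusted p = 0.026 with an estimated correlation). They include Flt3, the growth factor receptor of the dendritic lineage (1.69 ± 0.27, adjusted p = 0.0025), and Kmo, an enzyme of tryptophan breakdown (2.29 ± 0.3, adjusted p = 0.000364). Of the 15 neutrophil markers, 6 were lower and 9 did not pass, with 11 lower when adjusted over the list alone. As a group they had a median of -0.66 (adjusted p = 2.11e-17, adjusted p = 0.0456 with an estimated correlation). These are the only 2 of 145 list calls over all comparisons that held with an estimated correlation, a test run only without the replicate block. The 12 Ly6C-high monocyte genes lay lower as a group although none passed singly and 2 were lower when adjusted over the list alone. The list median was -0.43 (adjusted p = 5.39e-06, adjusted p = 0.266 with an estimated correlation). Of the 10 MHC class II genes, Ciita, the master regulator of the class II genes, was 2.15-fold higher (8.84 ± 0.38 against 7.73 ± 0.19, adjusted p = 0.00212), 9 did not pass, and 4 were higher when adjusted over the list alone. Together their median stood at 0.25 (adjusted p = 2.49e-05, adjusted p = 0.266 with an estimated correlation). Of the 22 resident-type macrophage genes, only Timd4, a receptor for dying cells, passed (8.96 ± 0.44 against 6.91 ± 0.11, 4.15-fold, adjusted p = 5.88e-05), with 2 higher when adjusted over the list alone. This list had a median of 0.25 (adjusted p = 0.000254, adjusted p = 0.473 with an estimated correlation).

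The 13 T and NK cell markers lay higher in the Gr1-negative cells of day 1 (2 passed, 2 when adjusted over the list alone, median 0.43, adjusted p = 0.00013, adjusted p = 0.503 with an estimated correlation), beside the Klr genes. The 29 cell cycle genes (3 higher, 6 when adjusted over the list alone) had a median of 0.19 and an adjusted p of 3e-05 (adjusted p = 0.618 with an estimated correlation). The 17 genes of lipid handling had none past the test and 5 higher when adjusted over the list alone. The median of the list was 0.28 (adjusted p = 0.000223, adjusted p = 0.295 with an estimated correlation). The 10 mast cell and eosinophil markers had a median of 0.56 with none past the test and 4 higher when adjusted over the list alone (adjusted p = 0.014, adjusted p = 0.364 with an estimated correlation), and their adjusted p was 0.0826 without day 1 Gr1-negative replicate 2. The 3 sort markers measured did not pass without a block. Ly6g, a part of the Gr1 epitope, differed by -0.7 ± 0.18 (adjusted p = 0.0795, 0.0139 with the replicate number as a block). Cx3cr1 differed by 0.46 ± 0.25 (adjusted p = 0.676, 0.0195 with the block) and Adgre1, the gene of F4/80, by 0.1 ± 0.09 (adjusted p = 0.915). The other sort markers, Ly6c1 and Ly6c2, were not analysed, so the Ly6C that names the subsets was not tested. No call was made for the 3 sort markers as a list (median 0.1, adjusted p = 0.843), the inflammatory cytokines (-0.08, 0.399), glycolysis (-0.03, 0.412), oxidative phosphorylation (0.02, 0.498), matrix remodelling (0.03, 0.155), cell isolation stress (0.05, 0.885), B cell (-0.06, 0.4), fibroblast (-0.02, 0.422), muscle (-0.06, 0.087), endothelial (-0.14, 0.181) and red cell markers (-0.09, 0.374), each given as median and adjusted p. Iron and heme genes had a median of 0.13 and a mean of -0.15 (adjusted p = 0.708). Alternative activation genes gained a call with the block (median 0.12, adjusted p = 0.0688 without and 0.0358 with it, and adjusted p = 0.624 with an estimated correlation and no block).

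In all, 171 genes differed between the subsets at day 1, 136 higher and 35 lower in Gr1-negative cells, 71 of them at least 2-fold. The count was 152 without the genes of the other-cell-type marker lists and 747 with the replicate number as a block (598 higher, 149 lower). It was 72 without day 1 Gr1-positive replicate 1, 98 without Gr1-positive replicate 2 and 76 without Gr1-negative replicate 2. The 35 lower genes became 88 without Gr1-positive replicate 3 (135 higher), 15 without Gr1-negative replicate 1 (134 higher), and 9, 11 and 12 without the 3 arrays above, in that order. Of 14 lists called, 8 kept their call whichever array was left out. Of these 14, repair growth factors, hypoxia response, fatty acid oxidation, lysosome and interferon-stimulated genes, not described above, lost theirs without at least 1 array.

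At day 2 the Gr1-negative cells were set apart by proliferation genes on top of the dendritic cell genes, and the Gr1-positive cells by monocyte and hypoxia genes. As lists, none of these differences held with an estimated correlation (adjusted p = 0.0988 or higher). The cell cycle, monocyte and hypoxia lists had also been called at day 1, the hypoxia list not with each array left out. Ccna2, the cyclin of DNA synthesis and mitosis entry, stood at 8.17 ± 0.25 against 6.51 ± 0.22, 3.16-fold higher in Gr1-negative cells (1.66 ± 0.3, adjusted p = 0.00574), and the replication helicase gene Mcm6 was 2.62-fold higher (8.9 ± 0.4 against 7.51 ± 0.38, adjusted p = 0.00396). Vcan, a matrix proteoglycan made by inflammatory monocytes, stood at 9.71 ± 1 against 12.04 ± 0.21 (-2.33 ± 0.39, adjusted p = 0.00333), and Plac8, high in Ly6C-high monocytes, differed by -1.78 ± 0.32 (adjusted p = 0.00501). Egln3, a prolyl hydroxylase induced by hypoxia, stood at 8.63 ± 0.34 against 10.39 ± 0.21 (-1.76 ± 0.28, adjusted p = 0.0022).

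Of the 29 cell cycle genes, 16 were higher in Gr1-negative cells at day 2 and 13 did not pass, with 23 higher when adjusted over the list alone. Across the list the median was 0.74 (adjusted p = 4.02e-20, adjusted p = 0.266 with an estimated correlation). Of the 12 monocyte genes, 5 were lower, 8 when adjusted over the list alone. For the whole list the median was -0.83 (adjusted p = 3.68e-09, adjusted p = 0.186 with an estimated correlation). Of the 16 hypoxia genes, 4 were lower, 9 when adjusted over the list alone, Ankrd37 among them (-1.29 ± 0.22, adjusted p = 0.0036). Their common median was -0.38 (adjusted p = 4.87e-07, adjusted p = 0.251 with an estimated correlation). The 16 fatty acid oxidation genes (3 higher, 5 when adjusted over the list alone) had a median of 0.33 and an adjusted p of 9.2e-06 (adjusted p = 0.493 with an estimated correlation), and the 17 lipid genes (2 higher, 8 when adjusted over the list alone) had 0.35 and 5.48e-06 (adjusted p = 0.263 with an estimated correlation). Resident-type macrophage genes were higher in 6 of 22, 8 when adjusted over the list alone. The members had a median of 0.38 (adjusted p = 1.11e-05, adjusted p = 0.364 with an estimated correlation). Beside these shifts, 8 of 10 dendritic cell markers were higher, 8 when adjusted over the list alone (median 1.18, adjusted p = 2.37e-11, adjusted p = 0.0988 with an estimated correlation), among them Ccr7 (2.13 ± 0.32, adjusted p = 0.00167) and Flt3 (1.71 ± 0.27, adjusted p = 0.0022). Neutrophil markers were lower in 6 of 15, 9 when adjusted over the list alone. Their median was -0.55 (adjusted p = 3.79e-08, adjusted p = 0.199 with an estimated correlation). Klrb1b was 8.89-fold and Klrd1 7.92-fold higher in Gr1-negative cells (adjusted p = 1.52e-06 and 0.000324). With the block, the repair growth factors (median 0.44, adjusted p = 0.0732 without and 0.00363 with it) and the T and NK cell markers (median 0.23, 0.129 and 0.015) also passed, and Ly6g passed at 0.0225 (-0.55, 0.104 without it). Without the block these lists had adjusted p = 0.295 and 0.83 with an estimated correlation. The repair growth factors were picked with knowledge of earlier work on such macrophages and are not independent evidence of a direction.

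At day 2, 705 genes differed, 569 higher and 136 lower in Gr1-negative cells, 115 at least 2-fold (74 higher, 41 lower). Normalizing the table by quantiles again left 458 genes. The block gave 2375 genes (1946 higher, 429 lower). Single arrays moved the count to 360 (without Gr1-positive replicate 1; 231 higher, 129 lower), 238 (Gr1-positive replicate 3), 122 (Gr1-negative replicate 2) and 198 (Gr1-negative replicate 3; 138 higher, 60 lower). Both day 2 arrays numbered 1 stand apart from the others of their group on the second principal component (17.2 against -17.9 and -12.8 in Gr1-positive cells, -13.5 against -28 and -27.9 in Gr1-negative cells). Leaving out both, an alternative chosen after the data were seen, gave 307 genes (218 higher, 89 lower), and array quality weights gave 3049 (2011 higher, 1038 lower). Of 12 lists called, 9 kept their call whichever array was left out.

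At day 4 Xcr1 and other dendritic cell genes were higher in Gr1-negative cells, while Siglech, Ccr9 and Cd8b1 were higher in Gr1-positive cells. Xcr1, the chemokine receptor of cross-presenting dendritic cells, stood at 9.57 ± 0.27 against 7.09 ± 0.21, 5.55-fold higher in Gr1-negative cells (2.47 ± 0.17, adjusted p = 3.33e-07). Fscn1, an actin-bundling protein of mature dendritic cells, was 4.07-fold higher (10.37 ± 0.59 against 8.35 ± 0.18, adjusted p = 0.00166), and Il12b, a subunit of interleukins 12 and 23, 2.6-fold higher (8.36 ± 0.32 against 6.98 ± 0.22, adjusted p = 0.00166). Siglech, a lectin of plasmacytoid dendritic cells, stood at 7.75 ± 0.09 against 9.69 ± 0.59 (-1.94 ± 0.22, adjusted p = 7.77e-05), the homing receptor Ccr9 at 7.19 ± 0.34 against 9.26 ± 0.62 (-2.07 ± 0.3, adjusted p = 0.00129), and the T cell coreceptor gene Cd8b1 at 8.1 ± 0.63 against 9.85 ± 0.66 (-1.75 ± 0.29, adjusted p = 0.00466).

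Of the 29 cell cycle genes, 11 were higher in Gr1-negative cells at day 4, 22 when adjusted over the list alone (median 0.78, adjusted p = 2.98e-26, adjusted p = 0.199 with an estimated correlation), among them the mitotic kinesin genes Cenpe (1.23 ± 0.21, adjusted p = 0.0052) and Kif20a (1.08 ± 0.18, adjusted p = 0.00448). Dendritic cell markers moved with them: 4 of 10 were higher, 6 when adjusted over the list alone (median 0.9, adjusted p = 5.16e-13, adjusted p = 0.0722 with an estimated correlation), Ccr7 among them (2.01 ± 0.32, adjusted p = 0.00303). Fatty acid oxidation genes had none past the test and 3 higher when adjusted over the list alone. As a group they had a median of 0.23 (adjusted p = 2.87e-05, adjusted p = 0.507 with an estimated correlation). Monocyte genes (1 of 12 lower, 3 when adjusted over the list alone, median -0.51, adjusted p = 1.4e-05, adjusted p = 0.266 with an estimated correlation) and neutrophil markers (1 of 15 lower, 10 lower and 2 higher when adjusted over the list alone, median -0.49, adjusted p = 6.69e-05, adjusted p = 0.277 with an estimated correlation) lay lower. The 13 T and NK cell markers had a median of -0.94 with none past the test and 8 lower when adjusted over the list alone (adjusted p = 0.000241, adjusted p = 0.507 with an estimated correlation), and their adjusted p was 0.0819 without Gr1-positive replicate 2. The block brought further calls at day 4: interferon-stimulated genes (median -0.24, adjusted p = 0.149 without and 0.000318 with it), fibroblast markers (0.43, 0.0802 and 6.51e-05), and singly Nkg7, a granule protein of cytotoxic lymphocytes (-1.59 ± 0.41, 0.0961 and 3.57e-05), Cpa3, a mast cell protease (3.24 ± 0.85, 0.0973 and 0.00256), and Postn, a matrix protein of fibroblasts (1.67 ± 0.8, 0.417 and 0.000836). Without the block the interferon and fibroblast lists had adjusted p = 0.869 and 0.821 with an estimated correlation.

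At day 4, 143 genes differed, 109 higher and 34 lower in Gr1-negative cells, 58 at least 2-fold. The count was 704 with the block (522 higher, 182 lower), 65 without Gr1-positive replicate 2 and 90 without Gr1-negative replicate 3. The direction depended on 1 array: without Gr1-positive replicate 3, 58 genes were higher and 76 lower. Array quality weights gave 180 higher and 136 lower. Of 9 lists called, 5 kept their call whichever array was left out.

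**Figure D2:**
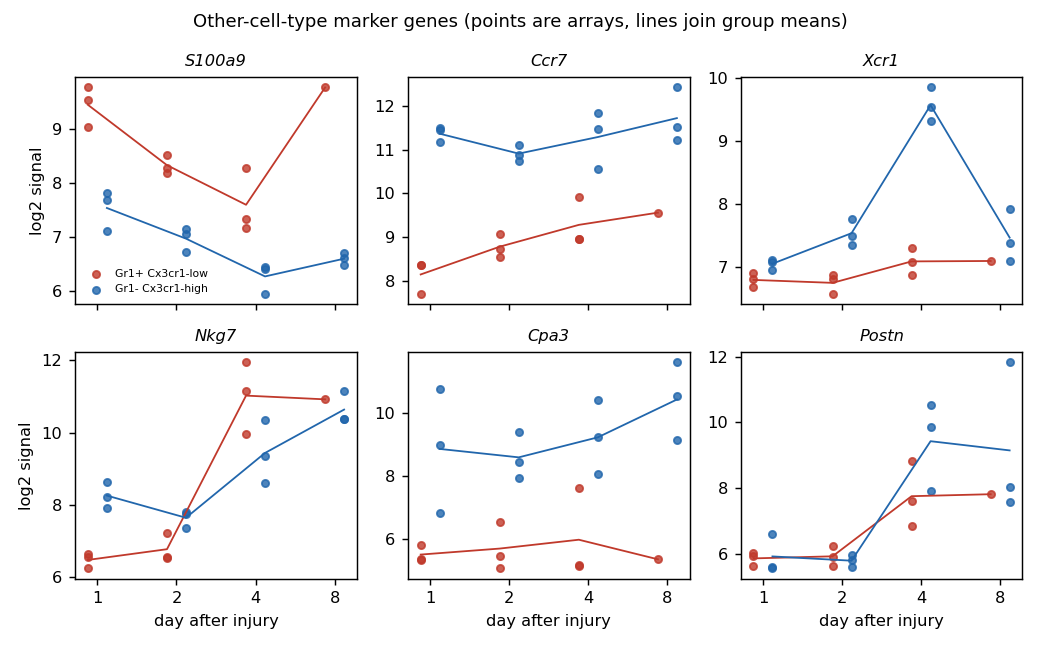
Log2 signal (vertical) of 6 marker genes of other leukocytes and of fibroblasts by day after injury (horizontal, evenly spaced), with 1 point per array and lines joining the means of the Gr1-positive (red) and Gr1-negative (blue) cells. S100a9 is higher in Gr1-positive cells at each day, Ccr7 in Gr1-negative cells, and Xcr1 reaches 9.57 in the Gr1-negative cells of day 4 against 7.09 in Gr1-positive cells.

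At day 8 the comparison rests on 1 Gr1-positive array, whose spread is assumed to be that of the other groups. Whether this sample was collected and pooled like the others is not known, so each difference at day 8 can belong to the sample rather than to the subset. Immunoglobulin genes were higher in that array: Igha, the heavy chain of immunoglobulin A, stood at 10.33 against 6.86 ± 0.26 (-3.47 ± 0.41, adjusted p = 0.000197) and Jchain, which joins immunoglobulin units, differed by -3.09 ± 0.31 (adjusted p = 2.63e-05). S100a9 stood at 9.78 against 6.59 ± 0.11 (-3.18 ± 0.35, adjusted p = 9.75e-05), the neutrophil collagenase gene Mmp8 at 9.06 against 6.33 ± 0.2 (-2.72 ± 0.33, adjusted p = 0.000248) and Vcan at 10.86 against 8.15 ± 0.36 (-2.72 ± 0.55, adjusted p = 0.0147). Ccl22 was 7.54-fold higher in Gr1-negative cells (10.45 ± 0.54 against 7.53, adjusted p = 0.000336), Il12b 3.55-fold (8.81 ± 0.58 against 6.98, adjusted p = 0.00313) and Ccr7 4.5-fold (adjusted p = 0.0184).

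Monocyte genes were lower in 6 of 12 at day 8, 7 when adjusted over the list alone (median -1.19, adjusted p = 3.68e-09, adjusted p = 0.186 with an estimated correlation), beside neutrophil markers lower in 6 of 15, 9 when adjusted over the list alone. The neutrophil markers had a median of -1.02 (adjusted p = 2.12e-10, adjusted p = 0.147 with an estimated correlation). Cell cycle genes were higher in 2 of 29, 13 when adjusted over the list alone (median 0.57, adjusted p = 1.29e-10, adjusted p = 0.364 with an estimated correlation), beside dendritic cell markers higher in 2 of 10, 5 when adjusted over the list alone. The dendritic cell markers had a median of 0.81 (adjusted p = 6.35e-05, adjusted p = 0.266 with an estimated correlation). Mast cell and eosinophil markers were higher in 4 of 10, 4 when adjusted over the list alone. This list had a median of 0.76 (adjusted p = 0.00317, adjusted p = 0.288 with an estimated correlation). T and NK cell markers had a median of -0.24 and a mean of 0.2 (adjusted p = 0.524). The block ended the calls of the resident-type genes (median 0.34, adjusted p = 0.0109, adjusted p = 0.626 with an estimated correlation, 0.262 with the block) and the muscle markers (0.27, adjusted p = 0.00263, adjusted p = 0.507 with an estimated correlation, 0.431 with the block). With the block this comparison rests on 1 array against 1, so lists that passed only with it are not reported.

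At day 8, 404 genes differed, 266 higher and 138 lower in Gr1-negative cells, 136 at least 2-fold. With only the compared groups in the fit 25 genes differed, 12 higher and 13 lower. Centring each array on its median gave 230 genes and the block, which there compares a single pair, 252 (190 higher, 62 lower). The count was 728, 215 and 160 without Gr1-negative replicates 1, 2 and 3.

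Between days 1 and 2, 76 genes were higher and 20 lower in Gr1-negative cells at both days, where 3.9 and 0.2 would be shared by independent lists, and none went opposite ways (r of the differences across genes 0.64). The days share no arrays, and genes are not independent replicates. Days 2 and 4 shared 33 higher (3.1 by chance) and 6 lower (0.2 by chance). At all of days 1, 2 and 4, 19 genes were higher, among them Ccr7, Ccl22, Clec9a, Timd4, H2-Ob and Klrb1b, and 3 were lower: Klra2, Ly6a2 and S100a9.

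**Figure D3:**
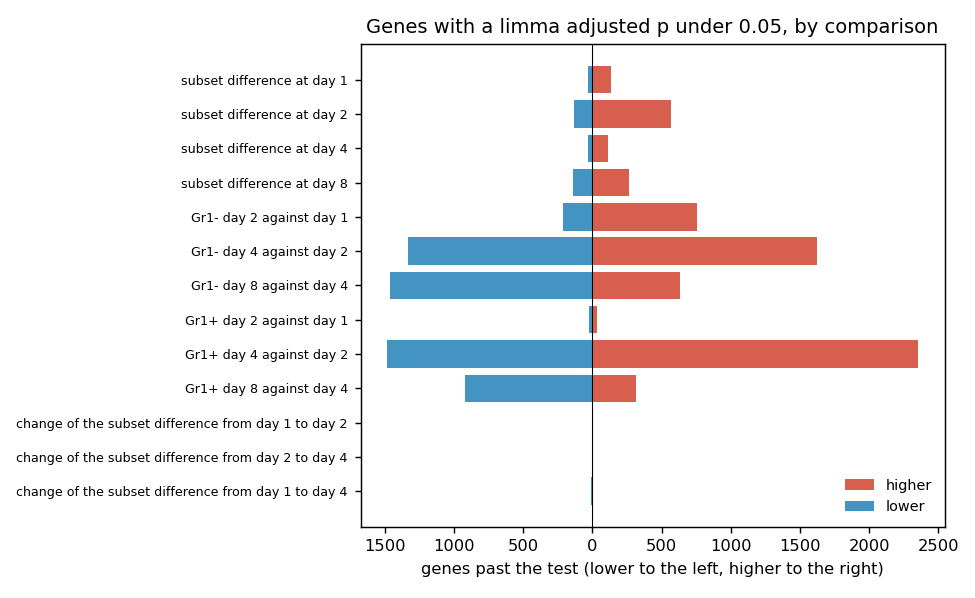
Numbers of genes past an adjusted p of 0.05 (horizontal; higher to the right, lower to the left) for each of the 13 comparisons (vertical). Day 4 against day 2 gave 3837 genes in Gr1-positive and 2957 in Gr1-negative cells, and the changes of the subset difference 0, 3 and 19.

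From day 1 to day 2 lipid and division genes rose in Gr1-negative cells, as did Igf1 and Gas6, while Vdr, Cd80 and Cd86 fell. The lipid and cell cycle lists had adjusted p = 0.186 and 0.266 with an estimated correlation. Igf1, a growth factor of muscle repair, rose 3.39-fold (9.59 ± 0.6 to 11.35 ± 0.06, adjusted p = 0.00254), and Gas6, a bridge between dying cells and their receptors, 3.96-fold (8.51 ± 0.33 to 10.49 ± 0.52, adjusted p = 0.00254). Lpl, which frees fatty acids from lipoproteins, rose 2.74-fold (1.46 ± 0.22, adjusted p = 0.00143) and Hadh, an enzyme of fatty acid oxidation, 2.6-fold (9.69 ± 0.31 to 11.07 ± 0.19, adjusted p = 0.000519). Vdr, the vitamin D receptor, fell from 10.74 ± 0.08 to 8.93 ± 0.11 (-1.81 ± 0.28, adjusted p = 0.00154), and the costimulatory ligand genes Cd80 and Cd86 fell by 0.87 and 0.8 (adjusted p = 0.00434 and 0.00139).

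Of 29 cell cycle genes, 14 rose in Gr1-negative cells by day 2, 24 when adjusted over the list alone (median 0.68, adjusted p = 1.14e-17, adjusted p = 0.266 with an estimated correlation), with Ccna2 up 3.08-fold (adjusted p = 0.00535). Of 17 lipid genes 7 rose, 10 when adjusted over the list alone, Fabp4 (1.31 ± 0.19, adjusted p = 0.00129) and Abcg1 (0.96 ± 0.14, adjusted p = 0.00143) among them. The median of the list was 0.49 (adjusted p = 2.81e-08, adjusted p = 0.186 with an estimated correlation). Fatty acid oxidation (5 of 16 rose, 12 when adjusted over the list alone, median 0.43, adjusted p = 4.79e-08, adjusted p = 0.364 with an estimated correlation), oxidative phosphorylation (3 of 27 rose, 14 when adjusted over the list alone, 0.3, 3.14e-08, adjusted p = 0.502 with an estimated correlation) and lysosome genes (3 of 17 rose, 6 when adjusted over the list alone, 0.15, 9.14e-05, adjusted p = 0.378 with an estimated correlation) also passed. Inflammatory cytokine genes fell in 3 of 20, 5 when adjusted over the list alone. Across the list the median was -0.29 (adjusted p = 6.31e-07, adjusted p = 0.364 with an estimated correlation). Monocyte genes fell in 3 of 12, 4 when adjusted over the list alone, Vcan among them (-2.13 ± 0.39, adjusted p = 0.00469). For the whole list the median was -0.5 (adjusted p = 1.38e-07, adjusted p = 0.229 with an estimated correlation). Alternative activation genes fell in 3 of 14, 6 when adjusted over the list alone. Their common median was -0.5 (adjusted p = 6.31e-07, adjusted p = 0.199 with an estimated correlation). Class II genes fell in 2 of 10, 4 when adjusted over the list alone; both that fell, Cd80 and Cd86, encode costimulatory ligands. The members had a median of -0.29 (adjusted p = 2.87e-05, adjusted p = 0.267 with an estimated correlation). Interferon-stimulated genes had 1 of 19 fall, 1 when adjusted over the list alone (Oas2, -1.2 ± 0.15, adjusted p = 0.000519; median -0.36, adjusted p = 3e-05, adjusted p = 0.588 with an estimated correlation).

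Neutrophil markers (1 of 15 fell, 1 when adjusted over the list alone, median -0.21) and T and NK cell markers (0 of 13 with limma, median -0.18) lay lower as well. Their adjusted p was 0.0215 and 0.0411, and adjusted p = 0.548 and 0.783 with an estimated correlation. Without day 1 replicate 2 or replicate 3 it was 0.217 and 0.0987 for neutrophil markers and 0.257 and 0.0639 for T and NK cell markers, and for the latter 0.0659 without day 2 replicate 1.

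In Gr1-negative cells 973 genes changed from day 1 to day 2, 757 up and 216 down, 147 at least 2-fold (89 up, 58 down). The repair growth factors as a list did not pass (1 up and 1 down of 10, median 0.05, adjusted p = 0.887). The count was 288 without day 1 replicate 1 (192 up, 96 down), 161 without day 2 replicate 2, 318 without day 2 replicate 3, and 2231 without both day 2 arrays numbered 1.

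In Gr1-positive cells fewer genes passed over the same step. Pparg, a nuclear receptor of lipid metabolism, rose 2.18-fold (9.76 ± 0.33 to 10.89 ± 0.08, adjusted p = 0.0045). Gpat3, an enzyme of glycerolipid synthesis, fell from 10.92 ± 0.27 to 9.98 ± 0.12 (-0.95 ± 0.11, adjusted p = 0.00217). Of the 17 lipid genes 4 rose, with 10 up and 1 down when adjusted over the list alone. Their median was 0.39 (adjusted p = 9.2e-06, adjusted p = 0.266 with an estimated correlation). Inflammatory genes (1 of 20 fell, 2 when adjusted over the list alone, median -0.25, adjusted p = 2.17e-07, adjusted p = 0.332 with an estimated correlation) and alternative activation genes (1 of 14 fell, 3 when adjusted over the list alone, -0.36, 5.19e-06, adjusted p = 0.238 with an estimated correlation) lay lower at day 2, beside the neutrophil markers (none past the test, 1 lower when adjusted over the list alone, -0.36, 9.96e-06, adjusted p = 0.266 with an estimated correlation).

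Only 58 genes passed in Gr1-positive cells, 32 up and 26 down. The count was 4, 26 and 259 without day 1 replicates 1, 2 and 3, and 955, 4 and 7 without day 2 replicates 1, 2 and 3. The balance moved as well, to 89 up and 170 down without day 1 replicate 3, 722 up and 233 down without day 2 replicate 1, and 1 up and 3 down without day 2 replicate 2. Quantile normalization gave 88 genes with 72.7% of them up, centring 21 with 42.9% up, and the filter on signal 123, where 55.2% of the 58 rose. Without both day 2 arrays numbered 1 it was 1225, 74.5% up. The subsets' day 1 to day 2 changes shared 25 genes up (1.2 by chance) and 16 down (0.3 by chance). The limma test of a difference between them called none without the block (lowest adjusted p 0.241) and 18 with it.

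From day 2 to day 4 both subsets lost injury-phase cytokine, glycolysis and hypoxia genes and gained division, interferon and lymphocyte genes. As lists, none of these shifts held with an estimated correlation (adjusted p = 0.119 or higher). Arg1, arginase 1, fell from 10.75 ± 0.38 to 7.2 ± 0.67 in Gr1-negative cells (-3.55 ± 0.32, adjusted p = 1.83e-06) and from 10.11 ± 0.32 to 7.6 ± 0.75 in Gr1-positive cells (-2.51 ± 0.32, adjusted p = 3.07e-05). Cxcl3, a chemokine for neutrophils, fell by 3.06 and 3.08 (adjusted p = 1.09e-05 and 6.97e-06). Cx3cr1, the fractalkine receptor used for the sort, rose 3.16-fold in Gr1-negative (9.15 ± 0.26 to 10.81 ± 0.32, adjusted p = 0.000156) and 3.15-fold in Gr1-positive cells (8.88 ± 0.42 to 10.54 ± 0.39, adjusted p = 0.000116). Dnase1l3, a secreted nuclease, rose 15-fold in Gr1-negative (5.97 ± 0.05 to 9.87 ± 0.4, adjusted p = 7.03e-08) and 8.62-fold in Gr1-positive cells (adjusted p = 8.38e-07). In Gr1-positive cells the cytotoxic lymphocyte genes Nkg7 (6.77 ± 0.39 to 11.03 ± 1, adjusted p = 2.67e-06) and Gzmb (3.47 ± 0.48, adjusted p = 6.01e-05) and the T cell gene Cd3g (3.54 ± 0.46, adjusted p = 3.03e-05) rose 19.1-fold, 11-fold and 11.7-fold.

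**Figure D4:**
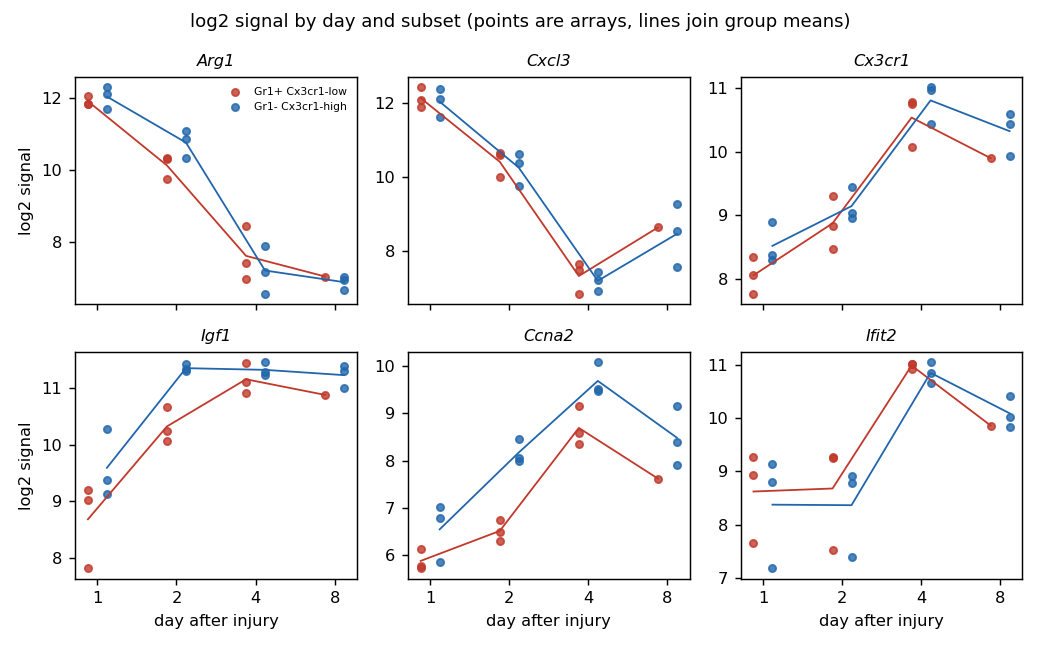
Log2 signal (vertical) of 6 genes by day after injury (horizontal, evenly spaced), with 1 point per array and lines joining the means of the Gr1-positive (red, 1 array at day 8) and Gr1-negative (blue) cells. Between days 2 and 4 Arg1 falls from 10.75 to 7.2 in Gr1-negative cells and from 10.11 to 7.6 in Gr1-positive cells, while Cx3cr1 and Ifit2 rise in both.

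In Gr1-negative cells from day 2 to day 4, 20 of 29 cell cycle genes rose and 1 fell, 21 and 1 when adjusted over the list alone (median 0.89, adjusted p = 1.6e-15, adjusted p = 0.277 with an estimated correlation), with the mitotic cyclin gene Ccnb2 up 3.96-fold (8.36 ± 0.37 to 10.34 ± 0.33, adjusted p = 6.83e-05). Of 19 interferon-stimulated genes 13 rose, 15 when adjusted over the list alone, among them Ifit2 (8.36 ± 0.84 to 10.85 ± 0.2, adjusted p = 0.00237) and Mx2 (1.53 ± 0.25, adjusted p = 0.000413). As a group they had a median of 1.0 (adjusted p = 2.05e-11, adjusted p = 0.332 with an estimated correlation). Of 20 inflammatory genes 11 fell and 1 rose, 11 and 3 when adjusted over the list alone, Cxcl1 (-1.87 ± 0.25, adjusted p = 5.31e-05) and Ccl7 (-1.25 ± 0.13, adjusted p = 8.55e-06) among them. The list median was -0.52 (adjusted p = 0.000283, adjusted p = 0.51 with an estimated correlation). Of 17 glycolysis genes 10 fell and 1 rose, 11 and 2 when adjusted over the list alone (median -0.46, adjusted p = 3.12e-05, adjusted p = 0.282 with an estimated correlation), with the glucose transporter gene Slc2a1 falling from 12.03 ± 0.28 to 10.55 ± 0.02 (adjusted p = 6.73e-06). Of 16 hypoxia genes 9 fell, with 12 down and 1 up when adjusted over the list alone, Vegfa (-1.28 ± 0.15, adjusted p = 2.02e-05) and Egln3 (-1.59 ± 0.28, adjusted p = 0.000623) among them. Together their median stood at -0.5 (adjusted p = 2.29e-06, adjusted p = 0.266 with an estimated correlation). Class II genes rose in 2 of 10, 2 when adjusted over the list alone, Ciita 4.28-fold (8.3 ± 0.16 to 10.4 ± 0.02, adjusted p = 8.76e-07). This list had a median of 0.27 (adjusted p = 0.00136, adjusted p = 0.364 with an estimated correlation). Resident-type genes rose in 5 of 22 and fell in 1, 5 and 1 when adjusted over the list alone, the dying-cell receptor gene Axl 3.69-fold (adjusted p = 0.000449) and Gpr34 5.5-fold (adjusted p = 0.000109). The median of the list was 0.25 (adjusted p = 0.00133, adjusted p = 0.507 with an estimated correlation).

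Markers of other cells moved at the same step in Gr1-negative cells. Dendritic cell markers rose in 7 of 10, 7 when adjusted over the list alone (median 1.15, adjusted p = 6.58e-08, adjusted p = 0.186 with an estimated correlation), Xcr1 4.08-fold (adjusted p = 1.41e-06) and Clec9a 3.88-fold (adjusted p = 1.33e-05). T and NK cell markers rose in 6 of 13 and fell in 1, 7 and 1 when adjusted over the list alone (median 1.01, adjusted p = 0.000184, adjusted p = 0.507 with an estimated correlation), Nkg7 3.46-fold (adjusted p = 0.00545). Postn rose 12.4-fold (5.79 ± 0.19 to 9.42 ± 1.36, adjusted p = 0.00364), and muscle markers rose in 5 of 15, 6 when adjusted over the list alone (median 0.26, adjusted p = 0.00126, adjusted p = 0.493 with an estimated correlation), the actin gene Actc1 2.22-fold (adjusted p = 0.000205). Cell isolation stress genes rose in 4 of 16 and fell in 1, 5 and 1 when adjusted over the list alone. Across the list the median was 0.24 (adjusted p = 0.00139, adjusted p = 0.364 with an estimated correlation). In all, 2957 genes changed, 1624 up and 1333 down, 451 at least 2-fold (339 up, 112 down). Array quality weights turned the balance to 2646 up and 3515 down. Without both day 2 arrays numbered 1 it was 1369 up and 1395 down. Quantile normalization again gave 1404 up and 1386 down.

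In Gr1-positive cells over that step 24 of 29 cell cycle genes rose, 25 when adjusted over the list alone (median 0.86, adjusted p = 1.53e-15, adjusted p = 0.277 with an estimated correlation), Ccna2 4.53-fold (adjusted p = 5.86e-05). Of 16 hypoxia genes 13 fell, 13 when adjusted over the list alone, Egln3 by 2.79 (adjusted p = 3.13e-06) and the disulfide-forming enzyme gene Ero1a by 1.76 (adjusted p = 1.32e-06). For the whole list the median was -1.06 (adjusted p = 1.36e-12, adjusted p = 0.119 with an estimated correlation). Of 17 glycolysis genes 12 fell and 1 rose, 13 and 1 when adjusted over the list alone. Their common median was -0.54 (adjusted p = 5.89e-07, adjusted p = 0.263 with an estimated correlation). Of 20 inflammatory genes 13 fell and 1 rose, 15 and 1 when adjusted over the list alone, Il6 by 2.57 (adjusted p = 3.97e-05). The members had a median of -0.72 (adjusted p = 1.88e-06, adjusted p = 0.364 with an estimated correlation). Of 12 monocyte genes 8 fell, 9 when adjusted over the list alone, Vcan by 2.79 (adjusted p = 6.11e-05). Their median was -0.9 (adjusted p = 0.000693, adjusted p = 0.364 with an estimated correlation). Resident-type genes rose in 13 of 22 and fell in 1, 14 and 1 when adjusted over the list alone, the complement gene C1qa 2.64-fold (10.59 ± 0.58 to 11.99 ± 0.16, adjusted p = 0.000237) and Axl 4.4-fold (adjusted p = 0.000108). As a group they had a median of 0.72 (adjusted p = 4.73e-06, adjusted p = 0.332 with an estimated correlation). Interferon-stimulated genes rose in 10 of 19, 14 when adjusted over the list alone, Stat2 2.83-fold (adjusted p = 5.81e-06). The list median was 0.81 (adjusted p = 5.61e-08, adjusted p = 0.463 with an estimated correlation). The cholesterol exporter gene Abcg1 rose 2.93-fold (adjusted p = 1.75e-06) and Ciita 5.75-fold (7.63 ± 0.2 to 10.16 ± 0.28, adjusted p = 6.22e-08).

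T and NK cell markers rose in 11 of 13 in Gr1-positive cells and fell in 1, 11 and 1 when adjusted over the list alone (median 2.17, adjusted p = 4.43e-09, adjusted p = 0.277 with an estimated correlation), beside dendritic cell markers in 6 of 10, 6 when adjusted over the list alone (median 1.52, adjusted p = 3.84e-06, adjusted p = 0.238 with an estimated correlation), Clec9a 4-fold (adjusted p = 7.54e-06). Neutrophil markers fell in 7 of 15 and rose in 1, 7 and 1 when adjusted over the list alone, Mmp8 by 1.63 (adjusted p = 7.03e-05). Together their median stood at -0.77 (adjusted p = 0.00345, adjusted p = 0.428 with an estimated correlation). Cell isolation stress genes rose in 5 of 16 and fell in 1, 5 and 1 when adjusted over the list alone (median 0.21, adjusted p = 0.00917, adjusted p = 0.493 with an estimated correlation), and their adjusted p was 0.0988 without day 2 replicate 3. In all, 3837 genes changed, 2353 up and 1484 down, 577 at least 2-fold (415 up, 162 down). Array quality weights gave 2751 up and 2932 down. No single array moved this count or that of the Gr1-negative cells by over 1.5 times. The subsets shared 1231 genes up (191.7 by chance) and 837 down (99.2 by chance), with 2 going opposite ways (r across genes 0.81). Their same-numbered arrays deviate together within a day, which adds to this overlap.

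From day 4 to day 8 the division genes fell again and cytokine genes rose in part, in lists whose adjusted p was 0.266 or higher with an estimated correlation. In Gr1-negative cells Il6, a cytokine of inflammation and muscle repair, rose 3.88-fold (7.2 ± 0.3 to 9.16 ± 0.51, adjusted p = 0.00321), Il10, an anti-inflammatory cytokine, 2.55-fold (adjusted p = 0.00237), and Pdgfb, a growth factor of mesenchymal cells, 2.16-fold (adjusted p = 0.00237). The mitotic kinase gene Plk1 fell by 1.26 (adjusted p = 0.00147) and Kif20a from 8.26 ± 0.27 to 6.83 ± 0.38 (adjusted p = 0.000275). Xcr1 fell from 9.57 ± 0.27 to 7.47 ± 0.41 (adjusted p = 5.4e-06), Cd5l, a secreted macrophage protein, from 8.44 ± 0.22 to 6.51 ± 0.22 (adjusted p = 0.00175), and Mmp8 from 8.99 ± 0.36 to 6.33 ± 0.2 (adjusted p = 6.37e-06).

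Of 29 cell cycle genes 18 fell in Gr1-negative cells by day 8, 24 when adjusted over the list alone. This list had a median of -0.6 (adjusted p = 1.1e-14, adjusted p = 0.288 with an estimated correlation). Of 27 oxidative phosphorylation genes 7 fell, 23 when adjusted over the list alone (median -0.38, adjusted p = 2.84e-09, adjusted p = 0.475 with an estimated correlation), and of 16 fatty acid oxidation genes 4 fell, 9 when adjusted over the list alone. The latter had a median of -0.36 (adjusted p = 3.72e-05, adjusted p = 0.507 with an estimated correlation). Inflammatory genes rose in 9 of 20, 12 when adjusted over the list alone (median 0.46, adjusted p = 8.05e-10, adjusted p = 0.266 with an estimated correlation), and isolation stress genes in 5 of 16, 5 when adjusted over the list alone, Klf2 among them (0.81 ± 0.14, adjusted p = 0.00299). The stress genes had a median of 0.27 (adjusted p = 1.87e-05, adjusted p = 0.266 with an estimated correlation). T and NK cell markers rose in 2 of 13, 3 when adjusted over the list alone (median 0.49, adjusted p = 0.00183, adjusted p = 0.602 with an estimated correlation), and their adjusted p was 0.101 without day 8 replicate 1. Dendritic cell markers fell in 4 of 10, 6 when adjusted over the list alone (median -0.77, adjusted p = 0.00321, adjusted p = 0.368 with an estimated correlation), while muscle markers rose in 7 of 15 and fell in 2, 7 and 2 when adjusted over the list alone (median 0.29, adjusted p = 0.00013, adjusted p = 0.373 with an estimated correlation), the muscle creatine kinase gene Ckm 2.05-fold (7.94 ± 0.05 to 8.98 ± 0.21, adjusted p = 2.42e-05).

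In Gr1-negative cells 2096 genes changed from day 4 to day 8, 632 up and 1464 down, 149 at least 2-fold (75 up, 74 down). With each array centred on its median 17.4% rose, where 30.2% of the 2096 did. The count was 523, 828 and 1318 without day 4 replicates 1, 2 and 3, and 592 and 547 without day 8 replicates 1 and 2 (40% and 40.2% up).

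The Gr1-positive cells of day 8, again 1 array, differed from day 4 most in immunoglobulin genes: Igha stood 17-fold higher (4.09 ± 0.41, adjusted p = 2.74e-05) and Jchain 15.2-fold higher (3.93 ± 0.31, adjusted p = 6.76e-07). Il6 stood at 8.62 against 6.29 ± 0.41 (adjusted p = 0.0115), S100a9 at 9.78 against 7.6 ± 0.61 (adjusted p = 0.00465) and Cxcl1 at 11.27 against 9.55 ± 0.32 (adjusted p = 0.0107). The spindle checkpoint gene Mad2l1 was lower by -1.55 ± 0.29 (adjusted p = 0.00773). Cell cycle genes fell in 8 of 29, 18 when adjusted over the list alone (median -0.67, adjusted p = 2.84e-09, adjusted p = 0.428 with an estimated correlation), oxidative phosphorylation genes in 8 of 27, 10 when adjusted over the list alone (median -0.44, adjusted p = 5.61e-08, adjusted p = 0.507 with an estimated correlation), and inflammatory genes rose in 6 of 20 and fell in 1, 11 and 1 when adjusted over the list alone. The inflammatory genes had a median of 0.58 (adjusted p = 1.84e-07, adjusted p = 0.332 with an estimated correlation). Neutrophil markers rose in 2 of 15, 3 when adjusted over the list alone. Their common median was 0.72 (adjusted p = 6.82e-05, adjusted p = 0.277 with an estimated correlation). Cell isolation stress genes moved with the inflammatory genes (1 of 16 rose, 2 when adjusted over the list alone, median 0.26, adjusted p = 0.000101, adjusted p = 0.282 with an estimated correlation). In all, 1238 genes passed, 316 up and 922 down, with 499 and 707 without day 4 replicates 1 and 2 and 775 with centred arrays. The subsets shared 145 genes up (10 by chance) and 480 down (67.7 by chance), and 1 went opposite ways.

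Tests of whether the subset difference changed between days called few genes. From day 1 to day 4 it rose for Xcr1 (2.21 ± 0.24, adjusted p = 0.000591) and fell for the plasmacytoid dendritic cell gene Siglech (-2.52 ± 0.31, adjusted p = 0.00167), for Ccr9 (-3.07 ± 0.43, adjusted p = 0.00365) and for the sodium pump subunit gene Atp1b1 (-2.58 ± 0.33, adjusted p = 0.002). Cell cycle genes moved towards Gr1-negative cells from day 1 to day 2 (none past the gene test, median 0.48, adjusted p = 7.49e-16, adjusted p = 0.277 with an estimated correlation) and from day 1 to day 4 (median 0.51, adjusted p = 7e-11, adjusted p = 0.364 with an estimated correlation; 14 up and 2 down when adjusted over the list alone). T and NK cell markers moved towards Gr1-positive cells from day 2 to day 4 (median -0.98, adjusted p = 1.26e-07, adjusted p = 0.332 with an estimated correlation; 6 when adjusted over the list alone) and from day 1 to day 4 (-1.37, adjusted p = 1.29e-10, adjusted p = 0.266 with an estimated correlation; 8 when adjusted over the list alone). Hypoxia genes moved towards Gr1-positive cells from day 1 to day 2 (-0.22, adjusted p = 0.00013, adjusted p = 0.33 with an estimated correlation). They moved back from day 2 to day 4 (0.45, adjusted p = 1.09e-08, adjusted p = 0.199 with an estimated correlation, 7 when adjusted over the list alone). Both changes use the same day 2 arrays, with opposite sign, so they are not independent.

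The difference changed for 0 genes from day 1 to day 2, 3 from day 2 to day 4 and 19 from day 1 to day 4 (7 up, 12 down). For the first, 649 had an unadjusted p under 0.05, fewer than chance gives. The block gave 18, 191 and 175 genes, and with it the lists of glycolysis (adjusted p = 0.0431), interferon (0.0201) and T and NK genes (0.00097) also passed from day 1 to day 2, inflammatory (0.0266) and interferon genes (0.0157) from day 2 to day 4, and dendritic cell markers (0.0447) from day 1 to day 4. With an estimated correlation and no block these lists had adjusted p = 0.669, 0.922, 0.825, 0.788, 0.869 and 0.783, in that order. The block put 52 up and 139 down from day 2 to day 4, and 71 up and 104 down from day 1 to day 4. Quantile normalization left 21.4% and centring 25% of the day 1 to day 4 genes up, where 36.8% of the 19 were, and centring left 2 genes from day 2 to day 4, 100% of them up against 66.7% of the 3. The day 1 to day 2 count was 1 without day 1 Gr1-positive replicate 1. The 3 genes of day 2 to day 4 became 0 without day 2 Gr1-positive replicates 1 or 3, day 2 Gr1-negative replicate 3 or day 4 Gr1-negative replicates 2 or 3, 1 without day 2 Gr1-negative replicate 2, 5 without day 2 Gr1-negative replicate 1 and 18 without day 4 Gr1-positive replicate 3 (2 up, 16 down). For days 1 to 4 the count was 8, 8 and 37 without day 1 Gr1-positive replicates 1, 2 and 3, 11 and 12 without day 1 Gr1-negative replicates 2 and 3, 11, 11 and 9 without day 4 Gr1-negative replicates 1, 2 and 3, and 10 and 48 without day 4 Gr1-positive replicates 2 and 3. The 37 were 24 up and 13 down, against 7 up and 12 down of the 19, and the 48 were 4 up and 44 down.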

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

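Each value here is a test of whether the difference between the Gr1-negative and Gr1-positive cells changed between days, with positive values for a move towards Gr1-negative cells. The second marker lists were predicted before they were tested, while the level-matched genes and the omission of pairs were tests chosen after the result was seen. The difference changed for 3 genes from day 2 to day 4 and for 19 from day 1 to day 4. From day 2 to day 4 these were Xcr1 (1.69), Gpat3 (1.1) and Atp1b1 (-2.07). From day 1 to day 4 the named ones were Gpr141b (2.45), Apol7c (2.38), Xcr1 (2.21), H2-M2 (1.4), Cdkn3 (1.26), Cd209d (-3.64), Nkg7 (-3.37), Ccr9 (-3.07), Atp1b1 (-2.58) and Siglech (-2.52).

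From day 1 to day 2 the lists whose subset difference changed, by their median, were monocyte genes (-0.42), cell cycle (0.48), hypoxia (-0.22), oxidative phosphorylation (0.12), fatty acid oxidation (0.15), lysosome (0.1), MHC class II (-0.36) and mast cell and eosinophil markers (-0.4). From day 2 to day 4 they were monocyte genes (0.23), resident-type genes (-0.3), repair growth factors (-0.35), hypoxia (0.45), lipid handling (-0.27), lysosome (-0.14), neutrophil (0.14), T and NK (-0.98) and fibroblast markers (0.52). From day 1 to day 4 they were repair growth factors (-0.31), cell cycle (0.51), hypoxia (0.18), oxidative phosphorylation (0.05), lipid handling (-0.14), MHC class II (-0.32), neutrophil (0.34), T and NK (-1.37) and fibroblast markers (0.45). None of these list changes held with an estimated correlation.

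The numbers of genes were also counted in regroupings of the same arrays, 100 for each change, fitted without the replicate block. All 100 reached the real count of 0 from day 1 to day 2, 13 reached 3 from day 2 to day 4 and 4 reached 19 from day 1 to day 4, with 1028, 857 and 304 genes in the highest other. These shares do not test chance. A regrouping that keeps the real subsets at 1 day, or at both with the labels of 1 day exchanged, carries the subset difference of those days. The highest counts came from such regroupings, the 304 from a regrouping that kept both days. Those that kept neither day reached at most 5, 0 and 2 genes. They mix the subsets within a group, which adds the subset difference to the spread, so they are no reference either. With the block the real counts were 18, 191 and 175.

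Dendritic cell markers, and at day 1 mast cell and eosinophil markers, lay higher in Gr1-negative cells as lists (with an estimated correlation adjusted p = 0.026, 0.0988 and 0.0722 for dendritic cell markers at days 1, 2 and 4, and 0.364 for mast cell markers). A second dendritic cell list, sharing no gene with the first and written before its test, had a median of 0.31 over days 1, 2 and 4 with 9 of 9 measured genes positive, its most abundant gene Wdfy4 at 9.93 against 9.64 at day 1. The first mast cell list had 0.41 over those days and did not pass. A second had 0.22 over those days and did not pass with an estimated correlation (unadjusted camera p = 0.202). At day 1 this second list had 0.54, with 9 of 9 measured genes positive and Tpsab1 at 8.83 against 6.66. Its unadjusted camera p at day 1 was 0.0316 with an estimated correlation, and 0 genes passed singly. It had only 0.1 at day 2 and 0.12 at day 4. Genes of matched level had -0.031 where the 2 first lists had 0.89, so the shift was not general to genes of that level. The median difference over all genes was 0, -0.027 and -0.033 at days 1, 2 and 4. A small median of matched genes was therefore likely beforehand, and it does not test a scaling between arrays. The values are consistent with dendritic cells in the Gr1-negative gate and leave mast cells open, though macrophages also express some of these genes, and a sort that excludes CD11c-high class II-high and Kit-positive cells would remove them.

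Neutrophil markers lay higher in Gr1-positive cells as a list (with an estimated correlation adjusted p = 0.0456, 0.199 and 0.277 at days 1, 2 and 4). The second neutrophil list had -0.5 over these days but -0.23 at day 4, where it did not pass, with 8 of 9 genes negative and its most abundant gene Chil1 at 9.59 against 11.03 at day 1. Monocyte genes had -0.56, as large, so that neutrophils in the gate and a monocyte state without neutrophils could not be told apart. Genes of matched level had -0.015 against -0.47 for the first list. They did not share its shift, which for the reason given above does not test a scaling. Gr1 antibodies bind Ly6G as well as Ly6C, and a sort with a Ly6G-specific antibody would remove neutrophils.

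T cell and plasmacytoid dendritic cell lists lay higher in Gr1-positive cells at day 4, though few members passed singly and the T and NK list had adjusted p = 0.507 with an estimated correlation. A second T cell list had -0.78 with 13 of 14 genes negative and 0 of 14 past the limma test (0 also of the 13 first markers; most abundant Cd28, 9.4 against 9.7, and Thy1, 8.4 against 9.71) and a plasmacytoid dendritic cell list had -0.37 with 8 of 8 negative and 1 past the test (most abundant Tcf4, 10.36 against 10.51). Both are consistent with such cells in the Gr1-positive gate, as both can carry Ly6C, and gating out CD3-positive and Siglec-H-positive cells would remove them. The T and NK list had -0.94 with all pairs and -0.96, -0.64 and -1.21 without pairs 1, 2 and 3, so its median does not come from a single pool alone. Its call was nevertheless lost without Gr1-positive replicate 2 (adjusted p = 0.0819), and the plasmacytoid genes were not tested in this way.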

How the results depend on the processing

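Alternatives were written before the data were examined, except 2 chosen later: leaving out both day 2 arrays numbered 1, or the cell type marker genes. Over named genes and alternatives, 12513 results stayed the same, 74 became stronger, 1589 weaker and none reversed. For lists 4559 stayed, 175 were stronger, 338 weaker and 4 reversed. Those that stayed include tests called in neither fit. Where a fit has fewer arrays it has fewer degrees of freedom. For all other changes the cause was not tested.

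The subset difference counted 171 genes at day 1, 705 at day 2, 143 at day 4 and 404 at day 8. With only the compared groups in the fit the counts were 113, 375, 60 and 25 (48% higher at day 8, against 65.8%), and with array quality weights 307, 3049 (66% higher, against 80.7%), 316 (57%, against 76.2%) and 1462. The replicate block as a fixed term gave 747, 2375, 704 and 252, as a random term 472, 1858, 447 and 767. An adjusted p under 0.01 left 71, 160, 64 and 85, and a 2-fold minimum 71, 115, 58 and 136. Leaving out 1 array gave 72 to 223 at day 1, 122 to 953 at day 2, 65 to 195 at day 4 (43.3% higher without Gr1-positive replicate 3) and 160 to 728 at day 8. Quantile normalization gave 458 at day 2 (72.3% higher, against 80.7%), centring on the median 230 at day 8. Without both day 2 arrays numbered 1 the day 2 count was 307. Taking out the listed cell type genes, a plain subtraction, left 152, 683 and 138 at days 1, 2 and 4.

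In Gr1-negative cells 973, 2957 and 2096 genes changed from day 1 to 2, 2 to 4 and 4 to 8. Array quality weights gave 2823, 6161 (42.9% up, against 54.9%) and 4777, an adjusted p under 0.01 left 268, 1648 and 366, and a 2-fold minimum 147, 451 and 149. Leaving out 1 array gave 161 to 1286, 1998 to 2543 and 523 to 2565. The fixed block, whose numbers do not pair across days, gave 1483 for day 1 to 2, and leaving out both day 2 arrays numbered 1 gave 2231. Centring left 17.4% of the day 4 to 8 genes higher, against 30.2%.

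In Gr1-positive cells the day 1 to 2 count of 58 was the least stable: 0 with only the compared groups, 1842 with array quality weights (68.2% up), 123 with the filter on signal, 88 with quantile normalization (72.7% higher, against 55.2%), 21 with centring (42.9% higher), 17 with a 2-fold minimum, 4 at an adjusted p under 0.01, 296 with the fixed block, 1225 without both day 2 arrays numbered 1 (74.5% higher) and 4 to 955 when leaving out 1 array. The 3837 genes of day 2 to 4 became 5683 with array quality weights (48.4% up, against 61.3%), 2422 with only the compared groups, 2318 at an adjusted p under 0.01 and 577 with a 2-fold minimum, and 2997 to 3894 when leaving out 1 array. The 1238 of day 4 to 8 became 3168 with array quality weights, 182 at an adjusted p under 0.01, 240 with a 2-fold minimum, 792 with the fixed block, 775 with centring and 499 to 1284 when leaving out 1 array.

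The change of the subset difference counted 0, 3 and 19 genes from day 1 to 2, 2 to 4 and 1 to 4. The fixed block gave 18 (15 up, 3 down), 191 (52 up, 139 down) and 175 (71 up, 104 down), the random block 3, 48 and 91. Array quality weights gave 109 for day 2 to 4 (40.4% up) and 56 for day 1 to 4 (23.2% up). An adjusted p under 0.01 left 0 and 7 (14.3% up). For day 2 to 4 the filter on signal gave 8, quantile normalization 6 and centring 2 (100% up, against 66.7%). For day 1 to 4, only the compared groups in the fit gave 7, quantile normalization 14 (21.4% up, against 36.8%) and centring 8 (25% up). Leaving out 1 array gave 0 to 1, 0 to 18 and 8 to 48.

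Array weights were lowest for day 2 Gr1-positive replicate 1 (0.218), day 1 Gr1-negative replicate 1 (0.304) and day 4 Gr1-positive replicate 3 (0.486), and highest for day 2 Gr1-negative replicate 3 (2.889).

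Of 145 list calls, 2 held with an estimated correlation, both at day 1 (neutrophil and dendritic cell markers). The estimated correlation was not combined with the block. The number called ranged from 135 to 153 when leaving out 1 array. Interferon-stimulated genes reversed at day 1 without Gr1-negative replicate 1 (0.03 against -0.25; range over single arrays -0.40 to 0.03), and for Gr1-positive day 1 to 2 without day 2 replicate 1 (0.06 against -0.21; range -0.42 to 0.06) and without both day 2 arrays numbered 1 (0.06). Oxidative phosphorylation reversed in the change from day 1 to 2 without day 2 Gr1-positive replicate 1 (-0.01 against 0.12; range -0.01 to 0.19). Besides the list calls given in the report, the fixed block ended those of glycolysis in Gr1-negative cells from day 1 to 2 (adjusted p = 0.06) and of lysosome (0.0853) and interferon genes (0.275) in Gr1-positive cells from day 4 to 8, and added matrix remodelling in Gr1-positive cells from day 1 to 2 (0.0358) and endothelial markers from day 4 to 8 (0.0483). Apart from day 8 between the subsets, where it compares 1 array with 1, it changed no other list call, and no other call of a gene that the report names in a subset difference.

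The variance share of day, 27.7%, was 42.5% with the filter on signal, and 30.5% to 36.5% when leaving out 1 replicate number (SD 3.21), while that of subset, 7.1%, was 5% to 12.5% (SD 3.77). The number of arrays limits what the tests can see: with 1 array in a group, simulated changes of 1.5-fold were recovered in 25.4% of genes, against 69% with 3.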

Other observations

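Some genes outside the groups above moved strongly. Timp1, an inhibitor of matrix proteases, fell by 3.22 in Gr1-positive cells from day 2 to day 4 (adjusted p = 1.25e-05), and Mmp19, a matrix protease, by 1.7 in Gr1-negative and 1.83 in Gr1-positive cells. In Gr1-negative cells Mmp19 rose again by day 8, 2.62-fold (adjusted p = 0.00078). Pdpn, a glycoprotein of activated macrophages and stroma, fell by 2.39 in Gr1-negative cells from day 2 to day 4 (adjusted p = 1.24e-05). Il10 fell by 1.64 and 1.69 in Gr1-negative and Gr1-positive cells over that step. Cd4 rose 6.63-fold (6.99 ± 0.14 to 9.72 ± 0.02, adjusted p = 2.46e-10) and Ifng 6.82-fold (adjusted p = 2.55e-05) in Gr1-positive cells from day 2 to day 4.

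The regroupings of the arrays were set before the result was seen, and none was chosen after. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The other splits mix the compared groups, which adds any difference between them to the spread and can lower their counts. The real split alone reached its count (1 of 10) for the subset difference at day 1 (171, highest other 5, and 0 among splits that part all same-numbered pairs), day 2 (705, highest other 0) and day 4 (143, highest other 1), for Gr1-negative cells from day 1 to 2 (973, highest other 0), 2 to 4 (2957, highest other 0) and 4 to 8 (2096, highest other 69), and for Gr1-positive cells from day 2 to 4 (3837, highest other 1). For Gr1-positive cells from day 1 to 2, 2 of 10 splits reached 58, the real one and 1 that called 418. That split set replicates 1 and 3 of day 1 with replicate 1 of day 2. The rest formed its other group. Day 2 Gr1-positive replicate 1 thus sided with day 1 arrays, and without it the step called 955 genes.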
